A study of Mus musculus with 288 samples.

How the data were processed

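Genomic DNA of v-Abl transformed mouse pro-B cells, arrested with 3 µM STI-571 for 96 h with or without a DNA-PKcs inhibitor, was made into LAM-HTGTS libraries per the labels' protocols: sequence is amplified from a fixed bait end at Jκ into whatever it is joined to. The deposited file of a library is the junction table made by the authors: per the file headers, each line is 1 sequenced junction, given by the alignment positions of its bait and prey parts in the genome and in the read, a unit of positions with no normalization between libraries. Bowtie2 (version not stated) and genome build mm9 were used per the submitters' processing notes. Every filter column of the deposited tables is 0, so junctions that failed the authors' filters had been removed, and each read name occurs once among the 2660276 junctions. Repeated junctions were kept in most libraries (97.6% of JK1 CE junctions in WT repeat another of the same library, 12.5% in L4-/- PKcs-/- line #1), but in JK5 SE libraries the group means are at most 25.0%.

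Groups are the bait, its end and the genotype with its treatment, as the labels give them. The numbers of the replicates follow the order of the samples in the labels. All CE libraries were sequenced in 1 lane per the read names, SE libraries of JK1 and JK2 in another, and SE libraries of JK4 and JK5 in a further one, so every comparison within a bait is within a lane. Files for 181 of the 288 samples were analysed and 107 were not analysed here. Depth ranged from 25 to 377981 junctions per library (median 1529), and 3 libraries had under 50. Shares of single libraries or pools are given with 95% exact Clopper-Pearson intervals, and a count of 0 with the share that 3 counts would give. PCR copies are not independent molecules, so these intervals and limits cover counting error only. Nothing in the labels says that replicates are separate cultures, and libraries of different baits may share DNA, so the p values measure only the spread between samples.

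The Igk locus was taken as 4 Mb on the V side and 0.1 Mb on the C side of the bait break on chromosome 6, and prey outside it as off-locus. Distal junctions lie in the locus at least 5 kb from the break. The overlap of bait and prey in the read gave microhomology (1 bp or more), direct joining (none) or insertion. A bait end was called trimmed when it lay more than 5 bp from the most frequent end of that bait. Signal sequences were listed where SE baits joined exactly at a heptamer at least 20 times (118 sites), and distal prey within 500 bp of a site were read as signal end or coding end from their direction, which covered 90.2% of CE and 87.5% of SE distal junctions. Signal-end prey are hybrid-type joints for CE baits and signal joints for SE baits. The annotation at hand has another genome build, so V segments are not named and sites are mm9 windows of 10 kb. Antigen receptor loci were mm9 windows fixed before the data were examined: Igh on chromosome 12 from 114 to 118 Mb, Igl on 16 from 18 to 20, Tcra and Tcrd on 14 from 53 to 56, Tcrb on 6 from 40 to 42 and Tcrg on 13 from 19 to 20.

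Shares were computed per library with at least 50 junctions in the denominator. Groups were compared within each bait that had at least 2 libraries in both, the differences averaged over baits, and all relabellings within baits enumerated (exact permutation test, two-sided). The 2 lines of a genotype were pooled where both had enough junctions. Benjamini-Hochberg adjustment covered 262 tests (11 measures, 12 CE and 13 SE comparisons of 14 listed), and an adjusted p under 0.05 was called: 18 of the 50 tests of the main measures and 70 of all. Site use was compared with limma 3.58.1 on log2 of junctions plus 0.5 per 1000000 Igk junctions, for windows with a mean of at least 5 junctions and libraries with at least 200 distal junctions, in separate fits for groups with and without Lig4 and for each end type. The named windows are, per comparison, the 5 most used in the second group and up to 5 with the largest rise and fall among called windows of 1 sign in every bait. Off-locus windows are the 10 joined at least 2 times in the most libraries. The text gives a selection of these.

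Tested on simulated data, the permutation test gave p under 0.05 in 5.5% of 400 sets without a difference and in 100% with one of 3 SD. These sets had 4 baits of 6 against 3 libraries, the largest design here. Most comparisons are smaller, and in some no p under 0.05 is possible, so the 100% does not hold for them. With 4-fold changes put into the CE inhibitor comparisons, limma recovered 15 of 15, 14 of 15 and 14 of 15 windows, in the SE ones 8 of 18, 10 of 18 and 14 of 18, and for WT + DPKi #2 against WT 7 of 20 (CE) and 1 of 20 (SE). Over 19 comparisons it recovered 239 changed windows and called 14 unchanged ones, at most 3 in 1 comparison (beside 10 changed ones for SE L4-/- PKcs-/- against L4-/- and 15 for CE Ku70-/- L4-/- against L4-/- PKcs-/-). Libraries of 1 group were compared by window counts in 140 pairs, 43 of which had chi-square p of 0.05 or more. No pair had the same list of junctions, so none was treated as a copy. At most 8.08% of distinct molecules were shared in those 43, and up to 76.8% (JK2 SE WT) and 44.3% (JK1 CE WT + DPKi #2) in other pairs. Alternatives covered counting of copies, log odds, depth and library minimums, locus window, bait-proximal junctions, lines, baits, the microhomology definition, limma's filter, pseudocount, window size and centring, and leaving out each library. Counting copies by prey end, removing junctions also found in libraries of WT cells, treated or not, or prey in Igl, and tests between lines were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyarrow 21.0.0, matplotlib 3.10.9 and R 4.3.3 were used.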

Results

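The series maps joining at the mouse immunoglobulin kappa light chain locus, Igk, in pro-B cell lines transformed by v-Abl and arrested with 3 µM STI-571, an Abl kinase inhibitor, for 96 h, which induces cutting and joining of the V and J segments (V(D)J recombination). Its stated topic is the role of DNA-PKcs, the catalytic subunit of the DNA-dependent protein kinase. Each library lists sequenced junctions between a fixed bait end at 1 of 4 Jκ segments (JK1, JK2, JK4 or JK5) and its partner, the prey. Coding-end libraries (CE) start from the Jκ segment itself, and signal-end libraries (SE) from its recombination signal sequence. The genotypes are WT, L4-/- (no Lig4, the ligase of classical end joining), DPK-/- in 2 lines, Ku70-/- (no Ku70, part of the Ku complex that binds broken ends), L4-/- PKcs-/- in 2 lines and Ku70-/- L4-/-. WT and L4-/- cells were also treated with the DNA-PKcs inhibitors DPKi #1 (Nu7441, 0.5 µM) or DPKi #2 (Nu7026, 20 µM). The labels use DPK-/- where the series design lists PKcs-/-, and the label's name is kept here.

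The labels list 288 samples in 96 groups of 3. Files for 181 libraries were analysed, 98 CE and 83 SE, and the other 107 samples were not analysed here. Of the 80 groups with a file, 41 have 3 libraries, 19 have 2 and 20 have 1. Together the files hold 2660276 junctions, with 25 to 377981 per library and a median of 1529. Depth differed strongly between genotypes: with the JK1 CE bait, WT libraries held 177533 to 377981 junctions, Ku70-/- L4-/- libraries 18754 to 36256, L4-/- libraries 2656 to 4855, and L4-/- PKcs-/- libraries 120 to 217 in line #1 and 407 to 1788 in line #2. DNA input is not stated, so these totals are depth and not a rate of recombination.

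Values below are percentages per library, averaged within a bait and then over baits. A difference (± SE) is the first-named group minus the second, and p values come from exact, two-sided permutation tests within baits, with Benjamini-Hochberg adjustment over 262 tests. Only DPK-/- and L4-/- PKcs-/- have a further line in the labels. In comparisons of genotypes, the genotype therefore cannot be told apart from a difference between lines. The main measures are the share of microhomology among Igk junctions at least 5 kb from the bait break (1 bp or more shared by bait and prey) and the share of all junctions whose prey lies outside Igk (off-locus). Positions are mm9 windows of 10 kb on chromosome 6, named by their first base.

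The comparison of L4-/- PKcs-/- with L4-/- asks how loss of DNA-PKcs changes the joining that remains without Lig4. Microhomology at coding ends was 42.2% in L4-/- PKcs-/- against 69% in L4-/- (difference -26.8 ± 2.58, n = 24 and 12), lower in all 4 baits. Junctions with neither overlap nor insertion made up 37.7% against 15.4%. The bait end was kept more often, with 16.7% of junctions trimmed by more than 5 bp against 59.2%, and hybrid-type joints (a coding end joined to a signal end) made up 9.01% against 26.5%. Prey within 5 kb of the bait fell from 40.6% to 12.9% of junctions. The exact permutation test gave p = 2.01e-08 for microhomology, the smallest value this design allows (adjusted p = 1.05e-06). This p measures the spread between libraries and not between lines. The labels name no further L4-/- line, and line #1 of L4-/- PKcs-/- minus line #2 was -12.7. For JK1, microhomology was 69.7% ± 5.08 (SD, n = 3) in L4-/-, 17.9% ± 4.13 (SD, n = 3) in line #1 and 47.8% ± 8.77 (SD, n = 3) in line #2. Off-locus prey were 1.86% against 1.37%, a difference of 0.490 ± 0.325 that was not called (permutation p = 0.253, adjusted p = 0.402, higher in 4 of 4 baits), and which turned to -1.14 with identical junctions counted once. In JK1, 84.9% ± 7.85 (SD, n = 3) of the line #1 junctions and 38.7% ± 16.6 (SD, n = 3) of the line #2 junctions were also present in WT or inhibitor-treated WT libraries, against 26.9% ± 4.31 (SD, n = 3) in L4-/-. With JK4 these shares were 93.7%, 82.0% and 42%, and with JK5 95.2%, 88.1% and 56.5%. JK1 WT libraries had 14.7% microhomology and 0.744% trimmed bait ends, so carried-over WT reads would lower both shares in L4-/- PKcs-/-. Such reads may account for part of line #1 with JK1, and with JK4 and JK5 cannot be told apart from WT-like joining. Leaving out junctions shared with WT-type libraries removes more from L4-/- PKcs-/- than from L4-/-, which by itself shifts the shares. The microhomology difference was then -20.8 and the off-locus difference 4.40.

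**Figure D1:**
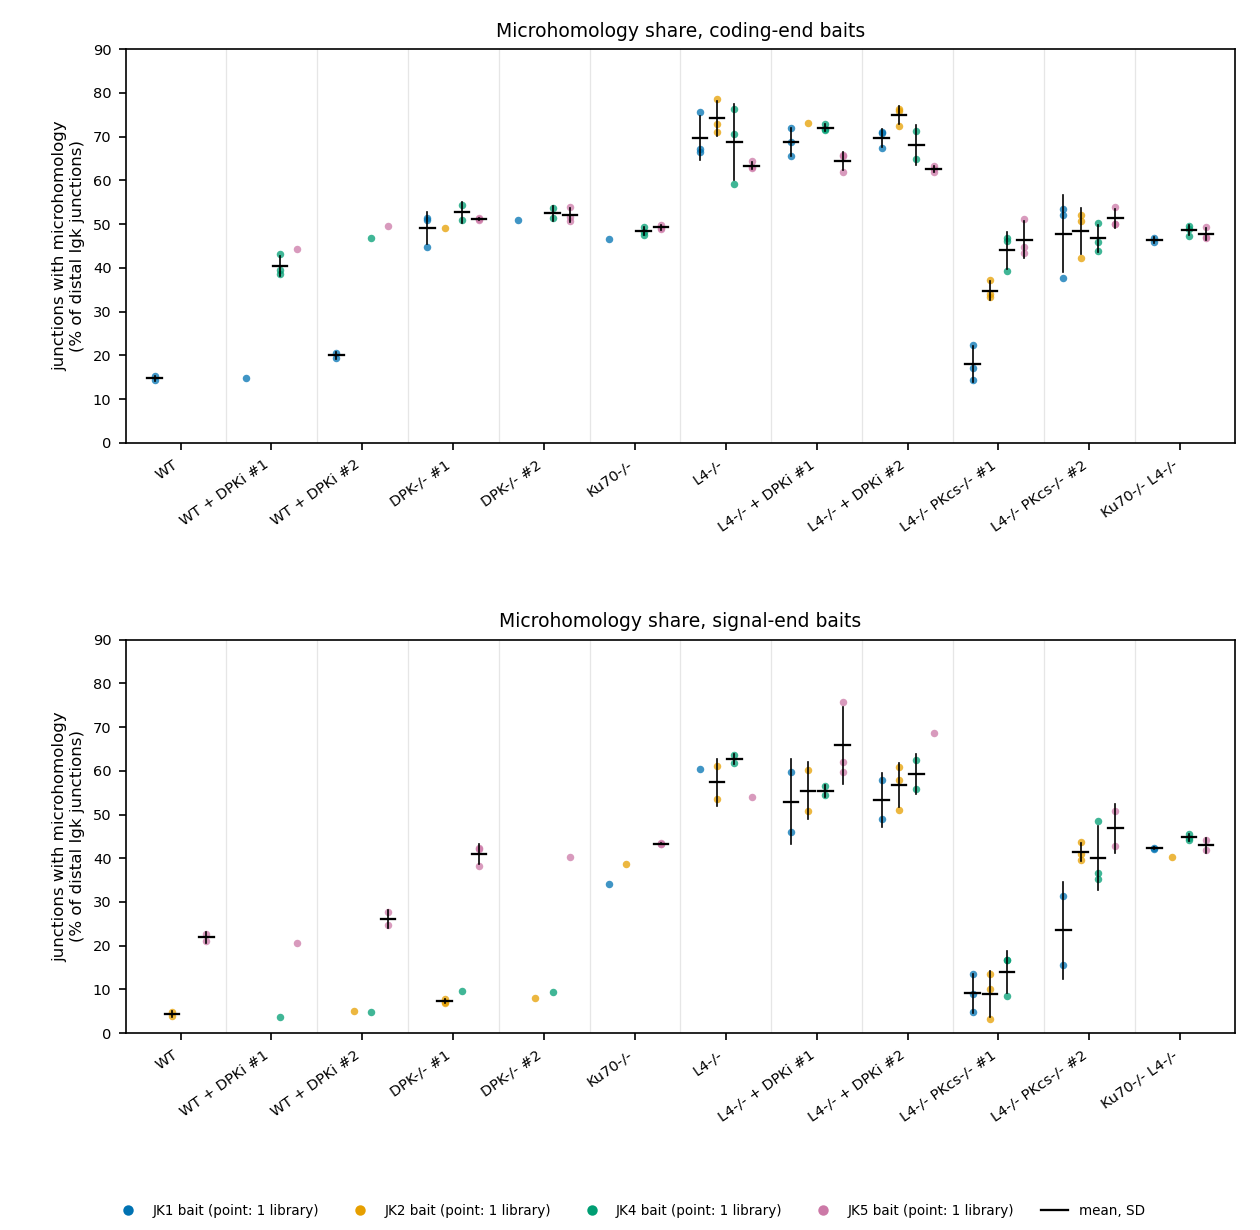
Microhomology share of distal Igk junctions (percent, y axis) per library (points) with group mean and SD (bars), by genotype and bait, for CE and SE baits. For JK1 CE, L4-/- averages 69.7%, Ku70-/- L4-/- 46.4% and WT 14.7%.

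Coding-end prey were fewer at the Jκ cluster and more frequent at many V segment windows. Of 76 windows tested with limma, 51 changed, 47 higher and 4 lower, and the median window was higher by 0.92 (log2). Prey within 5 kb of the bait were 4.91% in JK1 WT libraries, so carried-over WT reads would give a shift in this direction too. The fit held 19 of the 24 L4-/- PKcs-/- libraries. Line #1 weighs less in it, as its JK1 libraries had 120 to 217 junctions in all. Window 68990001 rose from 0.305% ± 0.286 (SD, n = 12) to 1.05% ± 0.479 (SD, n = 19) of Igk junctions (log2 change 2.23 ± 0.32 SE, limma adjusted p = 1.1e-07), and window 70290001 from 0.429% to 1.48%. The window that holds the Jκ segments and the baits, 70670001, fell from 38.0% ± 12.2 to 15.1% ± 10.6 (log2 change -1.67 ± 0.17 SE, limma adjusted p = 3.6e-11), as did its neighbour 70660001, from 4.32% to 1.51%. With each library centred on its own median window, which takes 0.94 off every log2 change, 27 passed, 8 higher and 19 lower. Without a filter on windows limma called 217 of 251, with identical junctions counted once 14 of 50, and among windows with a mean of at least 20 junctions 11 of 19.

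At signal ends the same genotypes differed in both main measures. Microhomology was 26.1% in L4-/- PKcs-/- against 60.05% in L4-/- (JK2 and JK4, n = 12 and 4, difference -33.9 ± 5.23, exact permutation p = 0.00128, the smallest possible, adjusted p = 0.00955, lower in 2 of 2 baits). Off-locus prey were 8.24% against 3.78% (JK2, JK4 and JK5, n = 15 and 7, difference 4.46 ± 1.29, exact permutation p = 0.00606, adjusted p = 0.0283, higher in 3 of 3 baits). In JK5, where libraries hold 84 to 113 and 86 to 97 junctions, the off-locus values were 13.9% ± 5.57 (SD, n = 3) in line #2 and 7.23% ± 2.67 (SD, n = 3) in L4-/-. limma called 21 of 91 windows, 19 higher and 2 lower, at a median shift of 0.90. All L4-/- PKcs-/- libraries in that fit were of line #2. Line #1 held 77 to 102 junctions with JK2 and 105 to 161 with JK4, under the 200 distal ones required. Centring each library on its own median window takes off 0.76 and left 5 higher and 6 lower. Window 67560001, at the far end of the V segments, rose from 0.322% ± 0.238 (SD, n = 4) to 1.95% ± 0.474 (SD, n = 6). Counting identical junctions once, limma called 9 of 59, with 2 added to the count 58 of 91, and without a filter on windows 101 of 226, so the count depends on how sparse windows are treated. The microhomology difference no longer passed without JK2 (-35.7) or JK4 (-32.2), the same test as without 1 of the 4 L4-/- libraries, or without junctions shared with WT libraries (-16.3). Junctions shared with WT-type libraries made up 89.8% (JK2) and 86.0% (JK4) of line #1, 29.5% and 39.4% of line #2, and 31.9% and 15.1% of L4-/-. The off-locus call ended at a minimum of 200 junctions per library, which leaves JK5 out (4.12), and in line #1 alone (2.64).

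The comparison of Ku70-/- L4-/- with L4-/- asks what Ku adds without Lig4. Microhomology at coding ends was 47.6% in Ku70-/- L4-/- against 67.3% in L4-/- (n = 8 and 9, difference -19.7 ± 1.98), lower in all 3 baits. Off-locus prey were 3.30% against 1.46% (1.85 ± 0.242), higher in all 3. Direct joints were 42.5% against 16.1%, and hybrid-type joints 39.5% against 23.0% (exact permutation adjusted p = 0.00252). Trimmed bait ends were 60.1% and 58.2% (exact permutation adjusted p = 0.557). Both main tests gave exact permutation p = 0.00025, the smallest possible (adjusted p = 0.00252). In JK5 the microhomology values were 47.7% ± 1.41 (SD, n = 3) and 63.4% ± 0.819 (SD, n = 3). With identical junctions counted once, the off-locus difference was 0.901 and no longer passed. limma called 33 of 76 windows, 25 higher and 8 lower, at a median shift of 0.09. Centring each library takes 0.40 off every log2 change, and the split was then 15 and 14. Without a filter 176 of 251 windows were called, 34 higher and 142 lower. Counting identical junctions once gave 20 of 50 windows, and with a mean of at least 20 junctions 14 of 19. Window 70190001 rose from 0.0627% ± 0.124 (SD, n = 9) to 0.941% ± 0.480 (SD, n = 8), a log2 change of 3.70 ± 0.55 (SE, limma adjusted p = 4.2e-07), and window 70330001 from 0.265% to 1.41%. Window 70660001 fell from 4.53% ± 2.68 to 0.414% ± 0.327 (log2 change -3.59 ± 0.32 SE, limma adjusted p = 2.7e-13), and window 69570001 from 2.46% ± 3.64 to 0.00469% ± 0.0149. The Jκ window itself held 32.4% and 33.9%. The labels name no further line of either genotype, so loss of Ku70 cannot be told apart from a difference between lines. Line #1 of L4-/- PKcs-/- minus line #2 was -12.7 in coding-end microhomology.

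At signal ends microhomology was 44.8% ± 0.804 (SD, n = 3) in Ku70-/- L4-/- and 62.7% ± 1.21 (SD, n = 2) in L4-/- with JK4, a design in which the exact permutation p cannot go below 0.1. Off-locus prey were 3.23% and 4.24% (n = 5 and 5, difference -1.01 ± 0.792, exact permutation p = 0.570, adjusted p = 0.698), higher in JK4 and lower in JK5. limma called 41 of 91 windows with JK4, 36 higher and 5 lower, at a median shift of 1.55, and 7 higher and 12 lower with libraries centred (1.11 taken off). Window 67560001 held 3.44% ± 0.0198 (SD, n = 3) against 0.212% ± 0.0323 (SD, n = 2), and the Jκ window 18.5% ± 2.94 against 49.9% ± 0.499. Of the 5 lower windows, 69620001 held no junction in either group and was called only through the pseudocount at different depths. Without L4-/- replicate 2 or 3, limma called 22 or 21 windows, with identical junctions counted once 14 of 59, and without a filter 159 of 226, most of them lower.

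Between the double knockouts, Ku70-/- L4-/- and L4-/- PKcs-/-, coding ends differed in how much of the bait end was lost. Trimmed bait ends were 60.1% without Ku70 and 16.1% without DNA-PKcs, where 82.0% to 95.2% of JK4 and JK5 junctions also occur in WT-type libraries, hybrid-type joints 39.5% and 9.59%, and insertions 9.90% and 20.0% (n = 8 and 18, permutation adjusted p = 9.13e-05 for hybrid-type joints and for insertions). Microhomology was 47.6% and 42.4% (difference 5.19 ± 2.52, permutation p = 0.286, adjusted p = 0.443, higher in 2 of 3 baits). Off-locus prey were 3.30% and 1.74% (difference 1.56 ± 0.365, exact permutation p = 0.00787, adjusted p = 0.0361, higher in 3 of 3 baits, n = 8 and 18). limma called 37 of 76 windows, 10 higher and 27 lower, at a median shift of -0.37, and 20 higher and 12 lower with libraries centred (a shift of -0.34 removed). The Jκ window held 32.4% ± 5.33 (SD, n = 8) against 16.2% ± 11 (SD, n = 15). Of 50 windows tested with identical junctions counted once, 23 were called, with a mean of at least 20 junctions 11 of 19, and without a filter 200 of 251. Against line #2 alone the off-locus difference was 0.798 and did not pass. Without junctions shared with WT libraries the differences turned, to -13.0 for microhomology and -2.17 for off-locus prey.

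With signal-end baits, microhomology was 43.3% in Ku70-/- L4-/- and 29.6% in L4-/- PKcs-/- (n = 7 and 13, difference 13.8 ± 2.93, exact permutation p = 0.0133, adjusted p = 0.0499, higher in 2 of 3 baits), and insertions 1.67% and 6.09% (adjusted p = 0.0013). Off-locus prey were 3.04% and 6.93% (n = 7 and 14, difference -3.89 ± 1.11, exact permutation p = 0.0742, adjusted p = 0.176, higher in 1 of 3 baits). limma called 5 of 91 windows: 68290001 and 68250001 were higher, 69000001 and 68810001 lower, and the remaining one, 69620001, held no junction in either group. With JK4, line #1 of L4-/- PKcs-/- held too few junctions to enter this fit. Without JK1 Ku70-/- L4-/- replicate 3 limma called 3, without JK1 L4-/- PKcs-/- line #1 replicate 3 it called 8, and without JK4 line #2 replicate 1 it called 9. With 2 added to the count it called 39, and without a filter on windows 139 of 226. Leaving out 1 library at a time moved the microhomology difference between 6.92 and 22.6, and 14 of 20 libraries ended the call when left out. The call also ended with line #2 alone (6.51), with identical junctions counted once (9.05) and for microhomology of 2 bp or more (1.27). The difference turned without junctions shared with WT libraries (-11.5, with off-locus prey at -9.26), and limma called 1 window with identical junctions counted once.

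The inhibitor comparisons in L4-/- cells ask whether blocking DNA-PKcs acts like its loss. Microhomology at coding ends with either inhibitor stayed within the spread of the L4-/- libraries, 68.4% with DPKi #1 against 67.3% (difference 1.17 ± 2.08, n = 9 and 9, exact permutation p = 0.607, adjusted p = 0.730, higher in 2 of 3 baits) and 68.9% with DPKi #2 against 69% (difference -0.127 ± 1.81, n = 11 and 12, permutation p = 0.947, adjusted p = 0.975, higher in 2 of 4 baits). Trimmed bait ends were 60.2% and 59.3% with the inhibitors against 58.2% and 59.2%. The Jκ window held 34.0% ± 11.5 (SD, n = 9) of Igk junctions with DPKi #1 against 33.9% ± 11.3 (SD, n = 9) without inhibitor over 3 baits, and 39.6% ± 14.1 (SD, n = 11) with DPKi #2 against 38.0% ± 12.2 (SD, n = 12) over 4. limma called 0 of 76 windows for either inhibitor, with 3 and 5 windows at an unadjusted p under 0.05. At signal ends, microhomology was 55.4% with DPKi #1 and 57.9% with DPKi #2 against 60.05% (differences -4.60 ± 3.07 and -2.11 ± 2.93, exact permutation adjusted p = 0.280 and 0.572, n = 4 and 5 against 4), lower in 2 of 2 baits for each. The exact permutation p cannot go below 0.0556 and 0.0167 in these designs, so neither difference could have been called. limma called 0 of 91 signal-end windows, with 6 and 8 at an unadjusted p under 0.05.

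At signal ends off-locus prey rose with DPKi #2, to 7.11% against 3.78% without inhibitor (n = 8 and 7, difference 3.33 ± 1.02, exact permutation p = 0.00833, adjusted p = 0.0364, higher in 3 of 3 baits), while at coding ends they were 1.83% against 1.37% (n = 11 and 12, difference 0.457 ± 0.191, p = 0.0222, adjusted p = 0.0746, higher in 4 of 4 baits). With DPKi #1 they were 3.44% against 3.78% at signal ends (-0.343 ± 0.753, n = 7 and 7, exact permutation adjusted p = 0.775, higher in 1 of 3 baits) and 1.29% against 1.46% at coding ends (-0.168 ± 0.221, n = 9 and 9, exact permutation adjusted p = 0.575, higher in 1 of 3 baits). The doses of the compounds differ, 0.5 µM Nu7441 and 20 µM Nu7026. Side by side, off-locus prey were 1.29% with DPKi #1 and 2.00% with DPKi #2 at coding ends (-0.712 ± 0.202, n = 9 and 8, exact permutation p = 0.0045, adjusted p = 0.0238, lower in 3 of 3 baits) and 2.77% and 5.55% at signal ends (-2.78 ± 0.763, n = 9 and 10, exact permutation p = 0.0025, adjusted p = 0.0177, lower in 4 of 4 baits). Microhomology was 68.4% and 66.9% at coding ends (1.59 ± 1.38, n = 9 and 8, exact permutation adjusted p = 0.374, higher in 2 of 3 baits) and 54.6% and 56.4% at signal ends (-1.82 ± 3.46, n = 6 and 7, exact permutation adjusted p = 0.656, lower in 3 of 3 baits), and limma called 0 windows between the inhibitors for either end type, with 3 and 2 at an unadjusted p under 0.05. The signal-end values rest largely on JK5, 15.1% ± 4.13 (SD, n = 3) with DPKi #2, 6.83% ± 2.70 (SD, n = 3) with DPKi #1 and 7.23% ± 2.67 (SD, n = 3) without inhibitor, in libraries of 86 to 137 junctions. Without JK5 the signal-end differences were 1.08 for DPKi #2 against none and -0.971 between the inhibitors, and neither passed. Nor did the coding-end difference between the inhibitors without JK5 (-0.589) or without JK4 (-0.625). The coding-end difference of DPKi #2 against none was called with identical junctions counted once (0.982). It was also called with same-prey-end copies counted once, with bait-proximal junctions left out, and for 3 of 23 libraries left out singly.

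The comparison of DPK-/- with WT asks what DNA-PKcs contributes where Lig4 is present. With the JK1 coding end, microhomology was 49.5% ± 3.17 (SD, n = 4) in DPK-/- and 14.7% ± 0.648 (SD, n = 2) in WT, trimmed bait ends 85.9% and 0.744%, hybrid-type joints 9.83% and 0.296%, and off-locus prey 3.39% ± 1.23 (SD, n = 4) and 0.147% ± 0.0163 (SD, n = 2). With 4 against 2 libraries the exact permutation p cannot go below 0.0667. At signal ends, DPK-/- microhomology rose to 24.1% from 13.1% (n = 8 and 4, difference 11 ± 0.712, exact permutation p = 0.00444, the smallest possible, adjusted p = 0.0238, higher in 2 of 2 baits), off-locus prey to 1.98% from 1.26% (difference 0.725 ± 0.131, exact permutation p = 0.00889, adjusted p = 0.0370, higher in 2 of 2 baits, n = 8 and 4) and trimmed bait ends to 25.7% from 4.23%. Signal joints (a signal end joined to a signal end) were 86.2% against 90.2% of signal-end junctions (exact permutation adjusted p = 0.0238). The rise in microhomology was 3.12 in JK2 and 18.9 in JK5, and with junctions that carry insertions left out of the total it was 1.79 and no longer passed. Of WT junctions, 93.2% were repeats with JK2 and 22.2% with JK5, so means over these baits mix shares that weigh copies differently. The off-locus difference was 0.112 without prey in the lambda light chain locus and 0.617 with identical junctions counted once, and passed in neither. Leaving out any 1 of the 4 WT libraries drops its bait, and ended the microhomology call and the off-locus call (off-locus difference 0.424 or 1.03).

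For JK1 coding ends limma called 9 of 126 windows, 6 higher and 3 lower. The Jκ window rose from 4.59% ± 0.718 (SD, n = 2) to 12.7% ± 1.79 (SD, n = 4), a log2 change of 1.54 ± 0.17 (SE, limma adjusted p = 3.9e-06), and window 68810001 fell from 1.98% to 0.892%. With libraries centred (a shift of -0.40 removed) the calls were 14 higher and 0 lower. limma called 49 of 116 with identical junctions counted once, 23 with 2 added to the count and 172 of 292 without a filter, and without DPK-/- line #1 replicate 1, line #1 replicate 3 or line #2 replicate 3 limma called 19, 18 or 17. Without WT replicate 2 or 3 it called 5 or 1. At signal ends limma called 31 of 129, 10 higher and 21 lower (11 and 13 with libraries centred): the Jκ window rose from 5.54% ± 2.74 (SD, n = 4) to 13.1% ± 4.32 (SD, n = 8), and window 70700001, on the constant-region side, fell from 1.13% ± 0.96 to 0.161% ± 0.186. Without JK5 WT replicate 2 the signal-end calls were 18.

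In WT cells treated with DPKi #2, JK1 coding-end microhomology was 20.0% ± 0.751 (SD, n = 2) against 14.7% ± 0.648 (SD, n = 2), off-locus prey 0.468% ± 0.198 against 0.147% ± 0.0163, and trimmed bait ends 1.71% against 0.744%. With the JK5 signal end, microhomology was 26.2% ± 2.12 (SD, n = 2) against 21.9% ± 1.26 (SD, n = 2) and off-locus prey 5.74% ± 0.645 against 2.35% ± 0.0523. With 2 against 2 libraries the exact permutation p cannot go below 0.333, and limma called 0 of 126 and 0 of 129 windows, with 3 and 6 at an unadjusted p under 0.05. No bait had both WT and WT + DPKi #1 in at least 2 libraries.

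For Ku70-/- against WT only the JK5 signal end had enough libraries. Microhomology was 43.3% ± 0.124 (SD, n = 3) without Ku70 and 21.9% ± 1.26 (SD, n = 2) in WT, insertions 1.88% ± 0.105 and 52.3% ± 5.33, trimmed bait ends 72.2% and 7.66%, and signal joints 63.8% and 82.5%. The high insertion share in WT is that of JK5: with the JK2 signal end, WT libraries had 3.86%. Repeated junctions made up 22.2% of WT junctions with JK5 and 93.2% with JK2, so the shares of these baits weigh copies differently. Off-locus prey were 2.06% ± 0.194 and 2.35% ± 0.0523. The exact permutation p cannot go below 0.1 with 3 against 2 libraries. Among junctions without insertions the microhomology difference turned to -1.89. limma called 43 of 129 windows, 13 higher and 30 lower, among them window 68890001, 2.40% ± 0.499 against 1.13% ± 0.16, and window 70190001, 0.995% ± 0.130 against 2.37% ± 0.147. Without WT replicate 2 or 3, limma called 17 or 12 windows.

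The comparison of DPK-/- with Ku70-/- sets loss of DNA-PKcs beside loss of Ku where Lig4 is present. At JK4 and JK5 coding ends, microhomology was higher in DPK-/-, 52.1% against 48.8% (n = 10 and 6, difference 3.29 ± 0.582, exact permutation p = 0.00034, the smallest possible, adjusted p = 0.00287, higher in 2 of 2 baits). Insertions were 13.9% against 4.24% and hybrid-type joints 12.9% against 30.4%, both with exact permutation adjusted p = 0.00287, while trimmed bait ends were 77.0% and 75.7% (adjusted p = 0.193). Off-locus prey were 2.23% against 1.57% (difference 0.668 ± 0.220, exact permutation p = 0.00884, adjusted p = 0.0370, higher in 2 of 2 baits, n = 10 and 6), and -0.0108 was left of that difference without the lambda light chain locus. The off-locus call also ended in line #2 alone, without JK4 or without JK5, and for 7 of 16 libraries left out singly (0.522 to 0.754 over all 16). limma called 15 of 126 windows, 7 higher and 8 lower: window 67560001 held 2.67% ± 0.351 (SD, n = 10) against 1.66% ± 0.275 (SD, n = 6), and window 70330001 held 0.357% ± 0.0830 against 1.02% ± 0.200. At the JK5 signal end microhomology was 40.8% ± 1.96 (SD, n = 4) and 43.3% ± 0.124 (SD, n = 3), off-locus prey 3.38% ± 0.511 and 2.06% ± 0.194 and insertions 12.3% and 1.88% (exact permutation adjusted p = 0.176, 0.0841 and 0.0841). The exact permutation p cannot go below 0.0286 in this design, the value for off-locus prey and insertions, so neither could have been called. limma called 16 of 129 windows, 13 higher and 3 lower, of which window 70210001 held 2.02% ± 0.524 against 0.558% ± 0.0482. Without Ku70-/- replicate 1, 2 or 3 it called 9, 6 or 9, with 2 added to the count 40, and without a filter 76 of 303.

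L4-/- PKcs-/- against DPK-/- and Ku70-/- L4-/- against Ku70-/- ask what Lig4 still does in each background. Coding-end baits were trimmed in 16.1% of junctions in L4-/- PKcs-/- and in 80.0% in DPK-/- (n = 18 and 14, permutation adjusted p = 1.07e-06). Carried-over WT reads, which stay possible in L4-/- PKcs-/-, would lower its trimmed share, as JK1 WT libraries had 0.744%. Microhomology was 42.4% against 51.2% (difference -8.86 ± 2.57, permutation p = 0.00799, adjusted p = 0.0361, lower in 3 of 3 baits) and off-locus prey 1.74% against 2.62% (-0.881 ± 0.397, p = 0.0460, adjusted p = 0.129, lower in 3 of 3 baits). The off-locus difference was called with either way of counting copies once, in line #1 alone and without JK1, and changed sign without prey in Igl. The microhomology difference was -3.27 with line #2 alone, -3.89 at a minimum of 200 junctions per library and -0.421 for microhomology of 2 bp or more, and passed in none of these. Without junctions shared with WT libraries, which make up most of the L4-/- PKcs-/- junctions with JK4 and JK5, it turned to 8.77 and the off-locus difference to 3.47. At signal ends off-locus prey were 8.24% against 1.55% (6.69 ± 1.18, n = 15 and 10, permutation p = 4.86e-06, the smallest possible, adjusted p = 9.13e-05, higher in 3 of 3 baits), microhomology 33.0% against 19.3% (13.8 ± 3.51, n = 14 and 10, permutation p = 0.00853, adjusted p = 0.0366, higher in 3 of 3 baits) and signal joints 84.9% against 96.2% (adjusted p = 0.0419). The signal-end microhomology difference turned to -3.22 with identical junctions counted once. In line #1 alone the signal-end off-locus and microhomology differences were smaller, and neither was called.

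Ku70-/- L4-/- coding ends had 48.2% microhomology against 48.8% in Ku70-/- (n = 6 and 6, difference -0.667 ± 0.597, exact permutation p = 0.305, adjusted p = 0.443), a difference that turned to 4.15 with insertions left out of the total and to 3.29 for 2 bp or more. Direct joints were 39.2% against 46.9%, and the mean length of microhomology 2.04 against 1.80 bp (exact permutation adjusted p = 0.0238 for each). The genotypes also differed in off-locus prey, 2.96% against 1.57% (1.39 ± 0.278, n = 6 and 6, exact permutation p = 0.005, the smallest possible, adjusted p = 0.0238, higher in 2 of 2 baits), in insertions, 12.7% against 4.24%, and in trimmed bait ends, 48.9% against 75.7%. The off-locus call ended without JK4 or without JK5, where fewer relabellings are possible. It also ended for 2 of 12 libraries left out singly (1.19 to 1.53 over all 12). At the JK5 signal end microhomology was 43.0% ± 1.65 (SD, n = 2) and 43.3% ± 0.124 (SD, n = 3), off-locus prey 3.49% ± 0.358 and 2.06% ± 0.194 and signal joints 85.3% and 63.8%, where the exact permutation p cannot go below 0.1.

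L4-/- against WT sets cells without Lig4 beside cells with it. JK1 coding-end microhomology was 69.7% ± 5.08 (SD, n = 3) against 14.7% ± 0.648 (SD, n = 2), hybrid-type joints 35% against 0.296%, prey within 5 kb of the bait 49.0% against 4.91%, and off-locus prey 2.17% ± 0.35 against 0.147% ± 0.0163, in a design whose exact permutation p cannot go below 0.1. With the JK2 signal end, microhomology was 57.4% ± 5.41 (SD, n = 2) against 4.37% ± 0.638 (SD, n = 2), and off-locus prey over JK2 and JK5 were 5.05% against 1.26% (difference 3.79 ± 0.797, n = 5 and 4, exact permutation p = 0.0167, the smallest possible, adjusted p = 0.0598, higher in 2 of 2 baits).

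Among off-locus prey, other antigen receptor loci were used to very different degrees. The lambda light chain locus Igl, on chromosome 16, took 63.6% of coding-end off-locus junctions in DPK-/- line #1 (1378 of 2167, 95% exact Clopper-Pearson interval 61.5 to 65.6), 57.1% in line #2 (1079 of 1889, 54.9 to 59.4), 41.5% in Ku70-/- (381 of 918, 38.3 to 44.8), 16.8% in WT (141 of 841, 14.3 to 19.5) and 2.03% in L4-/- (7 of 344, 0.822 to 4.15). With signal-end baits its share was 57.7% and 48.8% in the DPK-/- lines, 35.6% in Ku70-/-, 35.1% in WT and 0.926% in L4-/-. The windows of chromosome 16 starting at 19060001 and 19200001 held 1881 and 1367 junctions and were joined at least 2 times in 74 and 62 libraries. The T cell receptor gamma locus Tcrg, on chromosome 13, took 7.07% (179 of 2532, 6.10 to 8.14) in Ku70-/- L4-/- coding-end libraries and 7.66% (231 of 3016, 6.73 to 8.67) in signal-end ones, against 4.36% (40 of 918) in Ku70-/- coding-end libraries and 0.872% (3 of 344) in L4-/-. The pool of Ku70-/- L4-/- coding ends comes mostly from JK1 (2233 of 2532), and with JK4 the order was the other way, 2.21% ± 0.504 (SD, n = 2) in Ku70-/- L4-/- and 6.71% ± 1.99 (SD, n = 3) in Ku70-/-, while 1 JK5 library of Ku70-/- L4-/- had 5.17% against 0.575% ± 0.995 (SD, n = 3). In L4-/- PKcs-/- line #2 signal-end libraries Tcrg took 6.06% (18 of 297). The heavy chain locus Igh, on chromosome 12, held 5.71% (48 of 841) in WT, whose coding-end pool is 2 JK1 libraries, and 3.99% (101 of 2532) in Ku70-/- L4-/- coding-end libraries (3.19% and 3.82% with identical junctions counted once), and 0 of 344 in L4-/-, which allows up to 0.872%. Pools combine baits that differ in depth, and repeated reads of a molecule count separately, so the intervals cover counting error only.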

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

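The tests between the lines, of shared reads and of depth in this part were chosen after the result was seen, while the comparison of single libraries with WT follows a rule set before the data were examined.

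The lines of L4-/- PKcs-/- differed from each other. Line #1 had less microhomology than line #2 at coding ends, 35.8% against 48.6% (difference -12.7, n = 12 and 12, lower in 4 of 4 baits, permutation p = 0.000275, adjusted over 6 tests between lines 0.000825), and at signal ends, 10.7% against 35% (difference -24.3, n = 9 and 8, lower in 3 of 3 baits, exact permutation p = 0.00025, the smallest possible, adjusted p = 0.000825). The DPK-/- lines had 51.9% and 52.3% at coding ends (permutation p = 0.767).

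Coding-end junctions of both lines were often also present in libraries of WT cells with or without inhibitor. With JK1 the lines differed, 84.9% in line #1, 38.7% in line #2 and 26.9% in L4-/-, while with JK4 both were high (93.7% and 82.0%, L4-/- 42%), as with JK5 (95.2% and 88.1%, L4-/- 56.5%). Sampling noise at low depth is argued against by L4-/- libraries thinned to 116 junctions 1000 times, whose lowest microhomology share was 51.7%, above the 22.4% of the highest JK1 library of line #1. Random thinning cannot test whether carried-over reads weigh more in a small library. Reads of a WT library counted in line #1 may account for part of the sharing: 2 of the 3 JK1 libraries shared more junctions, down to the far end of the prey, with 1 library of WT cells (69.8%, exact Clopper-Pearson interval 60.6 to 78.0, and 69.5%, 59.8 to 78.1) than any other WT-type library did (at most 50.6% and 55.8%), while the remaining one shared 35.2% and L4-/- libraries 8.72% to 11.9%. For JK4 and JK5 this held in 0 of 6 libraries, with 49.9% to 55.9% shared, 42% to 52.4% in line #2 and 17.8% to 34.9% in L4-/-, so that read carry-over and true WT-like joining cannot be told apart there, since all WT-type libraries of these baits share many junctions. A difference between the lines themselves, for example in remaining DNA-PKcs, stays open and was not tested. At signal ends, 89.8% (JK2) and 86.0% (JK4) of line #1 junctions were also present in WT-type libraries. These shares were 29.5% and 39.4% in line #2, and 31.9% and 15.1% in L4-/-. Read carry-over was not tested at signal ends.

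Some groups had 1 library and stand outside the comparisons, and 10 of their 14 values lay above the highest WT library of the same bait with their whole interval. Off-locus prey were 1.35% in the JK1 CE library of Ku70-/- (exact Clopper-Pearson interval 1.21 to 1.5, WT 0.136% to 0.159%). The JK2 SE libraries had 1.67% in Ku70-/- (1.46 to 1.91), 3.07% in Ku70-/- L4-/- (2.67 to 3.51) and 0.500% in WT + DPKi #2 (0.434 to 0.573), against 0.156% to 0.178% in WT. The JK5 SE library of WT + DPKi #1 had 3.10% (2.62 to 3.64, WT 2.32% to 2.39%). Microhomology was 46.5% in the JK1 CE library of Ku70-/- (45.8 to 47.2, WT 14.3% to 15.2%), and 38.8% (37.8 to 39.7) and 40.4% (39.0 to 41.7) in the JK2 SE libraries of Ku70-/- and Ku70-/- L4-/- (WT 3.92% to 4.82%). In JK5 SE, the only library with at least 50 distal junctions had 54% in L4-/- (27 of 50, 39.3 to 68.2) and 68.7% in L4-/- + DPKi #2 (46 of 67, 56.2 to 79.4), against 21.0% to 22.8% in WT. The other 4 values come from WT cells with an inhibitor, and their intervals reach into the WT range, although 4.97% itself lies above it: off-locus prey 0.122% (0.0611 to 0.219) and microhomology 14.8% (14 to 15.6) with JK1 CE and DPKi #1, and microhomology 20.7% (19.5 to 22.0) with JK5 SE and DPKi #1 and 4.97% (4.76 to 5.19) with JK2 SE and DPKi #2.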

How the results depend on the processing

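Values are differences in percentage points or, for prey sites, numbers of windows called by limma. A call is an adjusted permutation p under 0.05. Over all settings other than a library left out, microhomology kept direction and call in 191 of 240 values and turned in 21, off-locus prey in 222 of 277 with 11 turned, and window counts stayed within 1.5 times in 81 and moved further in 37. Of 18 called differences, 2 kept their call under every such setting: CE microhomology in L4-/- PKcs-/- against L4-/- (adjusted p up to 0.00245) and in Ku70-/- L4-/- against L4-/- (adjusted p 0.00245 to 0.0238). Leaving out baits, lines or libraries lowers the number of relabellings and so raises the smallest possible p, and a window filter changes how many windows are tested. Removing junctions also in WT libraries takes unequal shares from the groups (of JK1 coding-end junctions 84.9% in L4-/- PKcs-/- line #1, 26.9% in L4-/- and 7.49% in Ku70-/- L4-/-), which moves both shares by construction, so changes there are no evidence on the comparisons. For all other changes the cause was not tested. Settings that left no bait with 2 libraries in both groups gave no value. Depth limits the JK5 signal-end libraries of L4-/- cells (86 to 137 junctions with or without inhibitor) and the JK1 coding-end libraries of L4-/- PKcs-/- line #1 (120 to 217). No paired analysis was possible because the labels give no replicate numbers that pair libraries of different groups. The settings on copies with the same prey end, junctions also in WT libraries and prey in Igl were chosen after the data were seen.

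With identical junctions counted once, SE microhomology lost its call in Ku70-/- L4-/- against L4-/- PKcs-/- (9.05). SE microhomology changed sign in L4-/- + DPKi #2 against L4-/- (0.148) and L4-/- PKcs-/- against DPK-/- (-3.22). CE off-locus prey lost its call in Ku70-/- L4-/- against L4-/- (0.901). SE off-locus prey lost its call in DPK-/- against WT (0.617). CE off-locus prey became called in L4-/- + DPKi #2 against L4-/- (0.982) and L4-/- PKcs-/- against DPK-/- (-1.18). CE off-locus prey changed sign in L4-/- PKcs-/- against L4-/- (-1.14). CE windows numbered 14 in L4-/- PKcs-/- against L4-/-, 20 in Ku70-/- L4-/- against L4-/-, 23 in Ku70-/- L4-/- against L4-/- PKcs-/- and 49 in DPK-/- against WT. SE windows numbered 9 in L4-/- PKcs-/- against L4-/-, 14 in Ku70-/- L4-/- against L4-/-, 1 in Ku70-/- L4-/- against L4-/- PKcs-/- and 1 in L4-/- + DPKi #2 against L4-/-. On the log-odds scale (values in log odds), no longer called for SE microhomology: Ku70-/- L4-/- against L4-/- PKcs-/- (0.784). No longer called for CE off-locus prey: Ku70-/- L4-/- against L4-/- PKcs-/- (0.841). SE off-locus prey changed sign in Ku70-/- L4-/- against L4-/- (0.0389). At a minimum of 200 junctions per library, CE microhomology lost its call in L4-/- PKcs-/- against DPK-/- (-3.89). CE off-locus prey was not called in Ku70-/- L4-/- against L4-/- PKcs-/- (1.22). No longer called for SE off-locus prey: L4-/- PKcs-/- against L4-/- (4.12), L4-/- + DPKi #2 against L4-/- (1.08) and L4-/- + DPKi #1 against L4-/- + DPKi #2 (-0.971). The sign of SE off-locus prey turned in Ku70-/- L4-/- against L4-/- (1.72). With baits of 3 or more libraries per group only, SE microhomology was not called in Ku70-/- L4-/- against L4-/- PKcs-/- (17.7) and L4-/- PKcs-/- against DPK-/- (17.7). CE microhomology changed sign in L4-/- + DPKi #2 against L4-/- (0.0211). Calls of CE off-locus prey ended in L4-/- + DPKi #1 against L4-/- + DPKi #2 (-0.625). SE off-locus prey was not called in L4-/- PKcs-/- against L4-/- (6.63), L4-/- + DPKi #2 against L4-/- (7.82) and L4-/- + DPKi #1 against L4-/- + DPKi #2 (-8.22). With bait-proximal junctions left out, calls of SE off-locus prey ended in L4-/- PKcs-/- against L4-/- (4.22). Newly called for CE off-locus prey: L4-/- + DPKi #2 against L4-/- (0.935). The sign of CE off-locus prey turned in L4-/- PKcs-/- against L4-/- (-0.178).

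With copies of the same prey end counted once, calls of SE microhomology ended in L4-/- PKcs-/- against DPK-/- (10.6). CE off-locus prey gained a call in L4-/- + DPKi #2 against L4-/- (0.618) and L4-/- PKcs-/- against DPK-/- (-1.21). CE off-locus prey turned in L4-/- PKcs-/- against L4-/- (-0.242). Without junctions also in WT libraries, SE microhomology lost its call in L4-/- PKcs-/- against L4-/- (-16.3). The sign of CE microhomology turned in Ku70-/- L4-/- against L4-/- PKcs-/- (-13.0), L4-/- + DPKi #1 against L4-/- (-0.247), L4-/- PKcs-/- against DPK-/- (8.77) and Ku70-/- L4-/- against Ku70-/- (1.74). The sign of SE microhomology turned in Ku70-/- L4-/- against L4-/- PKcs-/- (-11.5) and DPK-/- against Ku70-/- (3.77). CE off-locus prey became called in L4-/- PKcs-/- against L4-/- (4.40). SE off-locus prey became called in Ku70-/- L4-/- against L4-/- PKcs-/- (-9.26). CE off-locus prey changed sign in Ku70-/- L4-/- against L4-/- PKcs-/- (-2.17) and L4-/- PKcs-/- against DPK-/- (3.47). Without prey in Igl, SE off-locus prey lost its call in DPK-/- against WT (0.112). The sign of CE off-locus prey turned in DPK-/- against Ku70-/- (-0.0108) and L4-/- PKcs-/- against DPK-/- (0.570).

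In line #1 alone, no longer called for SE microhomology: L4-/- PKcs-/- against DPK-/- (1.68). CE microhomology became called in Ku70-/- L4-/- against L4-/- PKcs-/- (11.4). No longer called for SE off-locus prey: L4-/- PKcs-/- against L4-/- (2.64) and L4-/- PKcs-/- against DPK-/- (4.04). Newly called for CE off-locus prey: L4-/- PKcs-/- against DPK-/- (-1.89). CE off-locus prey turned in L4-/- PKcs-/- against L4-/- (-0.0296). In line #2 alone, no longer called for CE microhomology: L4-/- PKcs-/- against DPK-/- (-3.27). SE microhomology was not called in Ku70-/- L4-/- against L4-/- PKcs-/- (6.51). CE microhomology turned in Ku70-/- L4-/- against L4-/- PKcs-/- (-1.04). CE off-locus prey lost its call in Ku70-/- L4-/- against L4-/- PKcs-/- (0.798) and DPK-/- against Ku70-/- (0.444). CE off-locus prey gained a call in L4-/- PKcs-/- against L4-/- (1.01). Without JK1, calls of SE microhomology ended in Ku70-/- L4-/- against L4-/- PKcs-/- (6.92). CE off-locus prey became called in L4-/- PKcs-/- against DPK-/- (-0.872). Without JK2, SE microhomology lost its call in L4-/- PKcs-/- against L4-/- (-35.7), DPK-/- against WT (18.9) and L4-/- PKcs-/- against DPK-/- (11.8). SE off-locus prey was not called in L4-/- + DPKi #2 against L4-/- (4.60) and DPK-/- against WT (1.03). Without JK4, CE microhomology was not called in L4-/- PKcs-/- against DPK-/- (-9.69). No longer called for SE microhomology: L4-/- PKcs-/- against L4-/- (-32.2), Ku70-/- L4-/- against L4-/- PKcs-/- (11.8) and L4-/- PKcs-/- against DPK-/- (11.9). CE microhomology changed sign in L4-/- + DPKi #2 against L4-/- (0.0211). No longer called for CE off-locus prey: Ku70-/- L4-/- against L4-/- PKcs-/- (1.77), L4-/- + DPKi #1 against L4-/- + DPKi #2 (-0.625), DPK-/- against Ku70-/- (0.764) and Ku70-/- L4-/- against Ku70-/- (1.84). Calls of SE off-locus prey ended in L4-/- PKcs-/- against L4-/- (4.60), L4-/- + DPKi #2 against L4-/- (4.30) and L4-/- + DPKi #1 against L4-/- + DPKi #2 (-3.27). Without JK5, calls of CE microhomology ended in DPK-/- against Ku70-/- (4.21) and L4-/- PKcs-/- against DPK-/- (-11.9). SE microhomology was not called in DPK-/- against WT (3.12) and L4-/- PKcs-/- against DPK-/- (17.6). The sign of CE microhomology turned in L4-/- + DPKi #2 against L4-/- (0.0740) and Ku70-/- L4-/- against Ku70-/- (0.215). CE off-locus prey was not called in Ku70-/- L4-/- against L4-/- PKcs-/- (1.32), L4-/- + DPKi #1 against L4-/- + DPKi #2 (-0.589), DPK-/- against Ku70-/- (0.572) and Ku70-/- L4-/- against Ku70-/- (0.942). SE off-locus prey lost its call in L4-/- PKcs-/- against L4-/- (3.38), L4-/- + DPKi #2 against L4-/- (1.08), L4-/- + DPKi #1 against L4-/- + DPKi #2 (-0.971) and DPK-/- against WT (0.424). SE off-locus prey turned in Ku70-/- L4-/- against L4-/- (1.72).

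With microhomology of 2 bp or more, CE microhomology lost its call in L4-/- PKcs-/- against DPK-/- (-0.421). Calls of SE microhomology ended in Ku70-/- L4-/- against L4-/- PKcs-/- (1.27). CE microhomology turned in Ku70-/- L4-/- against L4-/- PKcs-/- (-0.754) and Ku70-/- L4-/- against Ku70-/- (3.29). SE microhomology turned in DPK-/- against Ku70-/- (1.82). With insertions left out, no longer called for CE microhomology: L4-/- PKcs-/- against DPK-/- (-6.37). SE microhomology lost its call in Ku70-/- L4-/- against L4-/- PKcs-/- (12) and DPK-/- against WT (1.79). CE microhomology changed sign in Ku70-/- L4-/- against L4-/- PKcs-/- (-0.0901), L4-/- + DPKi #2 against L4-/- (0.892) and Ku70-/- L4-/- against Ku70-/- (4.15). SE microhomology changed sign in Ku70-/- against WT (-1.89) and DPK-/- against Ku70-/- (2.29).

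With no filter on windows, windows called with CE baits numbered 217 in L4-/- PKcs-/- against L4-/-, 176 in Ku70-/- L4-/- against L4-/-, 200 in Ku70-/- L4-/- against L4-/- PKcs-/-, 172 in DPK-/- against WT, 12 in WT + DPKi #2 against WT and 9 in DPK-/- against Ku70-/-. Windows called with SE baits numbered 101 in L4-/- PKcs-/- against L4-/-, 159 in Ku70-/- L4-/- against L4-/-, 139 in Ku70-/- L4-/- against L4-/- PKcs-/- and 76 in DPK-/- against Ku70-/-. With a mean of at least 20 junctions per window, CE baits gave, as windows, 11 in L4-/- PKcs-/- against L4-/-, 14 in Ku70-/- L4-/- against L4-/- and 11 in Ku70-/- L4-/- against L4-/- PKcs-/-. SE baits gave, as windows, 25 in Ku70-/- L4-/- against L4-/- and 2 in Ku70-/- L4-/- against L4-/- PKcs-/-. Centred on the median window of each library, CE windows numbered 27 in L4-/- PKcs-/- against L4-/- and 14 in DPK-/- against WT. SE windows numbered 11 in L4-/- PKcs-/- against L4-/-, 19 in Ku70-/- L4-/- against L4-/- and 1 in L4-/- + DPKi #2 against L4-/-. In windows of 50 kb, windows called with CE baits numbered 1 in L4-/- + DPKi #1 against L4-/- and 4 in DPK-/- against WT. Windows called with SE baits numbered 3 in Ku70-/- L4-/- against L4-/- PKcs-/-, 17 in Ku70-/- against WT and 10 in DPK-/- against Ku70-/-. With 2 added to the count, CE baits gave, as windows, 23 in DPK-/- against WT. SE baits gave, as windows, 58 in L4-/- PKcs-/- against L4-/-, 39 in Ku70-/- L4-/- against L4-/- PKcs-/- and 40 in DPK-/- against Ku70-/-.

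Each library was also left out in turn (r1 is replicate 1 of a group). In the permutation tests a bait left with 1 library in a group drops out with it. For off-locus prey, differences had these ranges. CE Ku70-/- L4-/- against L4-/- PKcs-/- gave 1.40 to 1.74, uncalled without JK1 L4-/- PKcs-/- #1 r1 (1.49) or r3 (1.45) or JK4 Ku70-/- L4-/- r2 (1.43). CE L4-/- + DPKi #2 against L4-/- gave 0.374 to 0.534, called without JK2 L4-/- r3 (0.529), JK4 L4-/- r2 (0.534) or JK5 L4-/- r1 (0.531). CE L4-/- + DPKi #1 against L4-/- + DPKi #2 gave -0.805 to -0.619, uncalled without JK4 L4-/- + DPKi #2 r1 or r2 (-0.625). CE DPK-/- against Ku70-/- gave 0.522 to 0.754, uncalled without JK4 DPK-/- #1 r1 (0.670) or r2 (0.557), JK4 Ku70-/- r2 (0.522) or r3 (0.728) or JK5 Ku70-/- r1 (0.709), r2 (0.644) or r3 (0.651). CE L4-/- PKcs-/- against DPK-/- gave -1.06 to -0.682, called without JK1 L4-/- PKcs-/- #2 r1 (-1.06). CE Ku70-/- L4-/- against Ku70-/- gave 1.19 to 1.53, uncalled without JK4 Ku70-/- L4-/- r2 (1.19) or JK4 Ku70-/- r2 (1.25). SE L4-/- PKcs-/- against L4-/- gave 3.596 to 5.44, uncalled without JK4 L4-/- r2 or r3 (4.60) or JK5 L4-/- r2 (4.18) or r3 (4.23). SE Ku70-/- L4-/- against L4-/- gave -3.73 to 1.72, turned without JK5 Ku70-/- L4-/- r2 or r3 (1.72). SE L4-/- + DPKi #1 against L4-/- gave -0.696 to 0.171, turned without JK5 L4-/- + DPKi #1 r2 (0.163) or JK5 L4-/- r1 (0.171). SE L4-/- + DPKi #2 against L4-/- gave 2.54 to 4.60, uncalled without JK2 L4-/- + DPKi #2 r1 (3.01), JK2 L4-/- r1 or r3 (4.60), JK4 L4-/- + DPKi #2 r2 or r3 (4.30), JK4 L4-/- r2 or r3 (4.30), JK5 L4-/- + DPKi #2 r2 (2.54) or JK5 L4-/- r2 (3.05) or r3 (3.09). SE L4-/- + DPKi #1 against L4-/- + DPKi #2 gave -3.67 to -2.19, uncalled without JK4 L4-/- + DPKi #1 r2 or r3 (-3.27) or JK4 L4-/- + DPKi #2 r2 or r3 (-3.27). SE DPK-/- against WT gave 0.424 to 1.03, uncalled without JK2 DPK-/- #1 r2 (0.709), JK2 DPK-/- #2 r1 (0.721), JK2 WT r1 or r2 (1.03) or JK5 WT r2 or r3 (0.424).

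For microhomology the ranges were these. CE L4-/- + DPKi #1 against L4-/- gave -0.406 to 2.44, turned without JK4 L4-/- r1 (-0.406). CE L4-/- + DPKi #2 against L4-/- gave -1.31 to 0.828, turned without JK1 L4-/- + DPKi #2 r1 (0.178), JK1 L4-/- r2 (0.604), JK2 L4-/- + DPKi #2 r1 (0.175), JK2 L4-/- r3 (0.417), JK4 L4-/- + DPKi #2 r1 or r2 (0.0211) or JK4 L4-/- r2 (0.828) or r3 (0.0962). CE L4-/- PKcs-/- against DPK-/- gave -10.2 to -7.63, uncalled without JK1 DPK-/- #1 r2 (-8.70) or r3 (-8.66) or JK1 DPK-/- #2 r3 (-8.71). SE L4-/- PKcs-/- against L4-/- gave -36.1 to -31.7, uncalled without JK2 L4-/- r1 or r3 (-35.7) or JK4 L4-/- r2 or r3 (-32.2). SE Ku70-/- L4-/- against L4-/- PKcs-/- gave 6.92 to 22.6, uncalled without JK1 Ku70-/- L4-/- r2 or r3 (6.92), JK1 L4-/- PKcs-/- #1 r1 (12.9), r2 (13.3) or r3 (13.6), JK1 L4-/- PKcs-/- #2 r1 (13.8), JK4 Ku70-/- L4-/- r1 (13.9), r2 (13.6) or r3 (13.8), JK4 L4-/- PKcs-/- #1 r1 (13.1), r2 (13.1) or r3 (12.5) or JK4 L4-/- PKcs-/- #2 r1 (14.4) or r2 (14.3). SE DPK-/- against WT gave 3.12 to 18.9, uncalled without JK2 WT r1 or r2 (18.9) or JK5 WT r2 or r3 (3.12). SE L4-/- PKcs-/- against DPK-/- gave 11.9 to 17.6, uncalled without JK2 DPK-/- #1 r1 (13.8), r2 (13.7) or r3 (13.7), JK2 DPK-/- #2 r1 (13.8), JK4 DPK-/- #1 r1 (11.9), JK4 DPK-/- #2 r1 (11.9), JK4 L4-/- PKcs-/- #2 r1 (13.1) or r2 (13.2) or JK5 L4-/- PKcs-/- #2 r2 or r3 (17.6).

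For the number of windows called by limma the ranges were these, where a group left with 1 library stays in and is assumed to vary like the others. CE L4-/- + DPKi #2 against L4-/- gave 0 to 1, moved without JK2 L4-/- + DPKi #2 r1 (1). CE L4-/- + DPKi #1 against L4-/- + DPKi #2 gave 0 to 1, moved without JK5 L4-/- + DPKi #1 r2 (1). CE DPK-/- against WT gave 1 to 19, moved without JK1 DPK-/- #1 r1 (19) or r3 (18), JK1 DPK-/- #2 r3 (17) or JK1 WT r2 (5) or r3 (1). CE WT + DPKi #2 against WT gave 0 to 1, moved without JK1 WT + DPKi #2 r3 (1). SE Ku70-/- L4-/- against L4-/- gave 21 to 36, moved without JK4 L4-/- r2 (22) or r3 (21). SE Ku70-/- L4-/- against L4-/- PKcs-/- gave 3 to 9, moved without JK1 Ku70-/- L4-/- r3 (3), JK1 L4-/- PKcs-/- #1 r3 (8) or JK4 L4-/- PKcs-/- #2 r1 (9). SE L4-/- + DPKi #1 against L4-/- gave 0 to 2, moved without JK2 L4-/- r1 (1) or JK4 L4-/- + DPKi #1 r3 (2). SE L4-/- + DPKi #2 against L4-/- gave 0 to 1, moved without JK2 L4-/- + DPKi #2 r2 (1) or JK2 L4-/- r3 (1). SE DPK-/- against WT gave 18 to 39, moved without JK5 WT r2 (18). SE Ku70-/- against WT gave 12 to 34, moved without JK5 WT r2 (17) or r3 (12). SE DPK-/- against Ku70-/- gave 6 to 19, moved without JK5 Ku70-/- r1 (9), r2 (6) or r3 (9).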

Other observations

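The tests of Igl use, of copies and of prey length, and the counts over other groupings of libraries, were chosen after the results were seen, while the test of a few windows was chosen before.

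Where along Igk the prey lay also differed, as values with no test. With the JK1 coding end, the part of the 4 Mb window nearest the bait (of 3 equal parts) held 70.3% ± 2.05 (SD, n = 3) of distal prey in L4-/-, 55.5% ± 0.135 (SD, n = 2) in WT, 52.7% ± 0.475 (SD, n = 3) in DPK-/- line #1 and 52.4% ± 0.594 (SD, n = 2) in Ku70-/- L4-/-. The middle part held 21.1% ± 1.43 in L4-/- and 35.6% ± 0.249 in WT, and the far part 17.0% ± 0.662 in Ku70-/- L4-/- against 8.60% ± 0.685 in L4-/-. With either inhibitor the nearest part held 68.9% ± 2.95 (DPKi #1, n = 3) and 70.6% ± 2.57 (DPKi #2, n = 3) in L4-/-.

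The orientation of the join changed as well. Coding-end prey in the deletional arrangement were 36.9% in L4-/- PKcs-/- against 51.9% in L4-/- (n = 24 and 12, difference -15.0, permutation p = 2.01e-08, the smallest possible, adjusted p = 1.05e-06, lower in 4 of 4 baits), and 40.3% in DPK-/- against 50.0% in Ku70-/- (n = 10 and 6, difference -9.70, exact permutation p = 0.00034, the smallest possible, adjusted p = 0.00287, lower in 2 of 2 baits). JK1 WT libraries had 34.6%, so carried-over WT reads, which stay possible, would lower the share in L4-/- PKcs-/-. The orientation was not separated from hybrid-type joints, which also differed. They were 9.01% against 26.5% in the former comparison and 12.9% against 30.4% in the latter. Both inhibitors left it near 51.2% and 52.4% in L4-/- (exact permutation adjusted p = 1 and 0.817). In WT cells with DPKi #1, JK4 coding-end microhomology was 40.4% ± 2.33 (SD, n = 3), with no untreated WT library of that bait analysed here.

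Lambda light chain prey may be favoured in DPK-/- cells. Igl took 61.8% of off-locus junctions per library in DPK-/- and 43.9% in Ku70-/- with JK4 and JK5 coding ends (n = 10 and 6, difference 17.9, exact permutation p = 0.0017, adjusted over the Igl tests 0.0204, higher in 2 of 2 baits). Copies of a few molecules are argued against by the share with identical junctions counted once, 60.9% in DPK-/- line #1. The limit set for this check was 19.5%, the upper bound for WT with copies kept. Counted once like line #1, coding-end pools over baits had 58.1% in DPK-/- line #2, 42.6% in Ku70-/- and 11.2% in WT. A general rise of off-locus joining is argued against too, since -0.0108 percentage points of the 0.668 difference between DPK-/- and Ku70-/- were left without Igl. Other groups do not all go the same way: Igl took 2.27% (1 of 44) and 13.6% (32 of 235) of coding-end off-locus junctions in L4-/- PKcs-/- lines #1 and #2, 2.03% in L4-/-, 35.4% and 35.6% in WT with DPKi #1 and #2, and 16.8% in WT, whose pool holds only JK1. At signal ends the shares were 1.61% and 25.3% in lines #1 and #2. Whether Igl cutting or the choice of partner differs stays open, found and tested on the same data.

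Nu7026 (DPKi #2) may raise off-locus joining in L4-/- cells. Copies of a few molecules are argued against, since a difference remained with identical junctions counted once. It was 0.982 at coding ends and 4.04 at signal ends, beside 0.457 and 3.33 as deposited. Its larger size is no added support: coding-end off-locus junctions hold fewer copies than the rest (241 distinct of 344 in L4-/-), so counting once raises their share in both groups. JK5 signal-end libraries hold almost no copies (0% in L4-/-, 0.347% with DPKi #2), so the setting tests little there. Nor did a few windows take the prey: the 10 most used held 5.67% of 423 distinct junctions, which lay in 397 windows. Short prey aligned to the wrong place is argued against at coding ends only, where the median prey length was 2 bp above that without inhibitor (-8 to 14 in 95% of 1000 resamplings). At signal ends, where the rise was called, the difference of -5.5 bp (-33.5 to 22.5) leaves it open. An effect of the dose, which is higher than that of Nu7441, or on other kinases stays open and was not tested.

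The number of windows called by limma was set against other groupings of the same libraries, up to 100 for each comparison. The groupings move libraries within baits only, so chance differences between lines or cultures are not tested by them. Chance assignment of libraries is argued against for the following, where only 1 of 100 groupings, the real one, gave as many. At coding ends these are L4-/- PKcs-/- against L4-/- (51, highest other 24), Ku70-/- L4-/- against L4-/- (33, highest other 19), Ku70-/- L4-/- against L4-/- PKcs-/- (37, highest other 5) and DPK-/- against Ku70-/- (15, highest other 4). At signal ends they are L4-/- PKcs-/-, line #2 only, against L4-/- (21, highest other 10) and DPK-/- against WT (31, highest other 6, and 18 without JK5 WT replicate 2). For DPK-/- against Ku70-/- at signal ends it was 1 of 35, the smallest share that design allows (16, highest other 11). There the count depends on single libraries, with 9, 6 or 9 windows without JK5 Ku70-/- replicate 1, 2 or 3. With identical junctions counted once, L4-/- PKcs-/- against L4-/- fell to 14 at coding ends (highest other 9) and to 9 at signal ends, where 2 of 100 reached it (highest other 9). The signal-end count was 58 with 2 added to the count and 101 with no filter on windows, settings not set against other groupings. For Ku70-/- L4-/- against L4-/- PKcs-/- at signal ends 2 of 100 gave as many (5, highest other 5), and also 2 of 100 without the window that holds no junction (4, highest other 4). That count depends on the settings: it was 1 with identical junctions counted once, 39 with 2 added to the count, 139 with no filter on windows, 3 without JK1 Ku70-/- L4-/- replicate 3, 8 without JK1 L4-/- PKcs-/- line #1 replicate 3 and 9 without JK4 line #2 replicate 1. For the inhibitors in L4-/- the real count is 0, which every grouping reaches, so the groupings say nothing about chance there. All 100 did so for DPKi #1 against none (highest other 1), DPKi #2 against none (2) and #1 against #2 (2) at coding ends, and for #1 against #2 (2) at signal ends. At signal ends all 18 did so for DPKi #1 and DPKi #2 against none (highest other 2 and 1).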
